A study of Mus musculus with 6 samples.

How the data were processed

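RNA was extracted from frozen quadriceps muscle of mice fed normal chow, and only RNA with an integrity number above 7 was used, per the labels. Ribosomal RNA was depleted, stranded total RNA libraries were made with the TruSeq kit and sequenced on an Illumina HiSeq instrument after being combined into 2 pools, per the labels' protocols. The labels do not say which library was in which pool, so the pool entered no model. There were 3 libraries from Control mice carrying the floxed gene and 3 from mice labelled mDrp1HET, a heterozygous muscle-specific knockout of Drp1, whose gene is Dnm1l.

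The authors deposited 1 table of 11768 genes with a log2 value per gene and library and a p-value per gene. The deposited values are log2 CPM, reads scaled to a common library total, per the file headers. Their linear values summed to the same total in all 6 columns, and every value was above 0, so each listed gene exceeded 1 CPM in every library. The submitters' processing notes name FastQC, DESeq2 1.30.0 and the mouse genome build GRCm38. The aligner and the read counter were not given in the sources used here. The deposited p-value column equalled a two-sided equal-variance Student statistic computed on the 6 log2 columns, with a largest difference of 6.99e-13.

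Each column held a constant step per read and a constant offset, and this gave back whole reads for 100% of the values (tolerance 0.01 reads). Recovered reads totalled 64728022, 28664508 and 25019293 in Control replicates 1 to 3 and 15782298, 10394761 and 32372360 in mDrp1HET replicates 1 to 3. The lowest read number of any gene was between 11 and 66, depending on the library. Of the listed rows, 68 had no symbol and were kept under their Entrez number, and 17 symbols that had been turned into dates were restored from Entrez numbers with the RefSeq table of GRCm38.p6. Of the 13 protein-coding genes of the mitochondrial genome, 0 were found among the listed genes under the names searched, so none was analysed. No other column of sample values was present (0 columns).

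The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on the deposited log2 CPM, two-sided, Benjamini-Hochberg adjusted over the 11768 genes, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 46 lists that had at least 5 measured members. The lists, the tests and most alternatives were chosen before the data were examined. The plan did not say whether camera should use the intensity trend. An exploratory run without it called 14 lists, and the trend was then used as in the gene test, which called 16. Counts of members are also given adjusted over the list alone. For Dnm1l an exact two-sided permutation test was added, whose smallest p with 3 libraries against 3 is 0.1.

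Control replicate 1 and mDrp1HET replicate 3 were found to hold the same library. Since the labels do not tell which group it came from, it was assigned to neither. The planned comparison of 3 columns against 3 is given as labelled, and a comparison without both columns (2 Control and 2 mDrp1HET libraries) was added after the data were seen and is called the 4-library comparison. With 1 library in both groups, the labelled fold changes are drawn toward 0 and the apparent spread within groups includes the distance between the groups. The alternatives were median centring, quantile normalization, offsets of 1 and 0.1 CPM, minimum mean log2 CPM values of 1 and 3, other variance models, array weights and leaving out each library. Removal of each library's trend on transcript GC content (loess, span 0.3) and limma voom on the recovered reads were added after the data were seen.

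The genes named are Dnm1l and the measured complex II genes, the 5 genes with the smallest p in each direction when none passed the threshold, and up to 4 members with the smallest p in each list described. Where genes passed, the rule took up to 10 per direction with official symbols, a mean log2 CPM above 0 and groups that did not overlap. It was applied to the labelled comparison as planned, and to the 4-library comparison as an addition. Genes named outside the rule are said to be so. The values of 1 gene the rule takes in the 4-library comparison are not reported here, and it is kept in all counts.

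The methods were tested on simulated data with 11768 genes, 200 of them changed, in 10 runs per design, with the real means, library sizes and fitted variance prior. In the simulated 2 against 2 comparison, 18.7%, 88.8% and 97.7% of genes changed by 1, 2 and 3 on the log2 scale were found, and 5.91% of all calls were false. When the moderated variances were taken as true instead, 12.7% of the calls in that comparison were false. In the simulated 3 against 3 comparison with 1 library in both groups, 0 of the changed genes were found at any of these sizes and the median estimate at a true change of 3 was 1.98. With 3 separate libraries per group, 48.4%, 97.2% and 99.7% were found. A list of 20 members shifted by 0.6 had an unadjusted camera p under 0.05 in 10 of 10 runs of each design. A list that was not shifted did so in 0 of 10 runs with 3 separate libraries per group, in 1 of 10 with 1 library in both groups and in 1 of 10 in the 2 against 2 comparison. Simulated genes varied independently of each other and without a GC trend. The simulated rates of false calls therefore need not hold for the real data. Read recovery returned 100% of simulated reads exactly.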

Results

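Quadriceps transcripts were measured by total RNA sequencing in 3 libraries labelled Control and 3 labelled mDrp1HET, a label that stands for loss of 1 copy of the gene for Drp1 in muscle. Drp1 is the GTPase that divides mitochondria, and the study asked how it bears on complex II assembly and fatty acid oxidation. The table listed 11768 genes. Recovered reads ranged from 10394761 in mDrp1HET replicate 2 to 64728022 in Control replicate 1. The labels give each library its own number but do not state that these number separate animals, so p-values measure the spread between these libraries. Transcripts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in all 6 libraries, with Ddx3y between 6.80 and 7.77 log2 CPM.

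Control replicate 1 and mDrp1HET replicate 3 held the same library. Control replicate 1 had exactly 2 times the reads of mDrp1HET replicate 3 in 11334 of 11768 genes (96.3%), against at most 81 genes in the other 14 pairs of libraries. Their largest difference was 0.14 log2 CPM, and 19 genes differed by more than 0.01. A chi-square statistic per gene was 0.00367 for this pair and between 52.8 and 253 for the others, so the columns differed by less than the sampling noise and count as 1 sample. The labelled comparison of 3 against 3 columns therefore held 5 separate libraries, 1 of them on both sides.

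**Figure D1:**
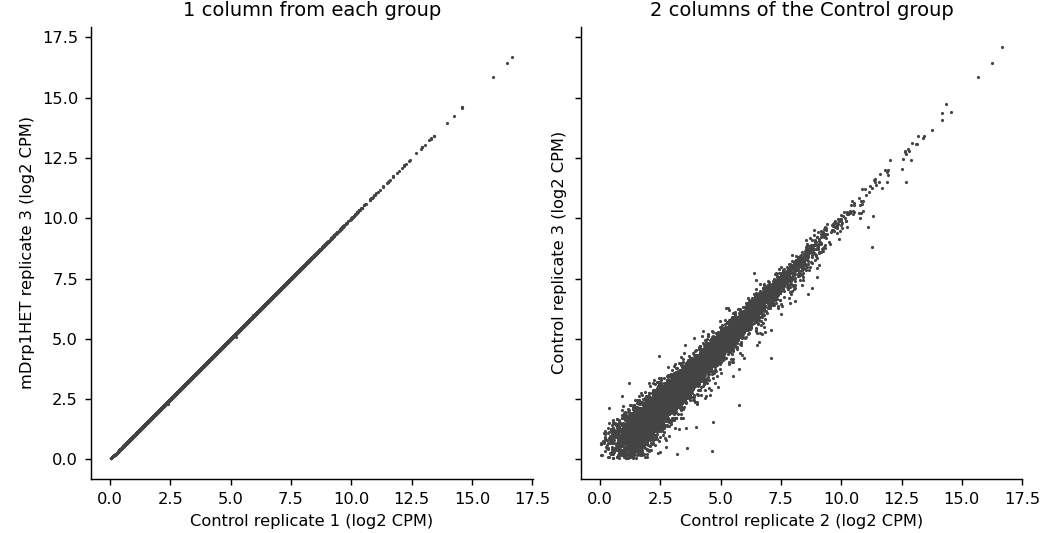
Deposited log2 CPM of 11768 genes, each gene a point, in Control replicate 1 against mDrp1HET replicate 3 (left) and in Control replicate 2 against Control replicate 3 (right). The left points lie on a line, with a largest difference of 0.14, and the right points scatter.

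Transcripts of Dnm1l, the targeted gene (Entrez 74006, chromosome 16, 16312228 to 16359038, RefSeq GRCm38.p6), were not detectably lower in the libraries labelled mDrp1HET. They stood at 6.69, 6.95 and 6.87 log2 CPM in Control replicates 1 to 3 and at 7.30, 6.73 and 6.69 in mDrp1HET replicates 1 to 3. The labelled log2 fold change was 0.07 (SE 0.19, 95% interval -0.36 to 0.50, limma adjusted p = 0.914). The exact permutation p was 0.9, where 0.1 is the smallest that 3 against 3 can give. Without both copies of the shared library, Dnm1l was 6.91 ± 0.06 (SD, n = 2) in Control and 7.02 ± 0.41 (SD, n = 2) in mDrp1HET libraries, a log2 fold change of 0.11 (95% interval -0.40 to 0.62). The sign turned with median centring (-0.04), quantile normalization (-0.01), array weights (-0.01), without Control replicate 1 (-0.0011) and without mDrp1HET replicate 1 (-0.13), and with removal of the GC trend (-0.09). Gene-level values do not separate intact transcripts from those of a recombined allele, and the directions below refer to the libraries labelled mDrp1HET.

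Complex II, the succinate dehydrogenase of the respiratory chain and the citric acid cycle, had 7 measured genes of 8 listed, and 0 passed the threshold in either comparison. Sdhaf2, the factor that helps attach the flavin cofactor to Sdha, was 5.12 ± 0.35 (SD, n = 2) in Control and 5.18 ± 0.31 (SD, n = 2) in mDrp1HET libraries, with a 4-library log2 fold change of 0.06 (95% interval -0.51 to 0.63). Sdha, the catalytic subunit, was 9.23 ± 0.42 against 8.43 ± 0.37 (SD, n = 2 each), a log2 fold change of -0.80 (SE 0.26, limma adjusted p = 0.195). The log2 fold changes of Sdhb and Sdhc were 0.40 (SE 0.37) and 0.13 (SE 0.29). Those of the assembly factors Sdhaf1, Sdhaf3 and Sdhaf4 were -0.04, 0.74 and 0.31. As a group the list did not pass (camera adjusted p = 0.598 in the labelled comparison).

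**Figure D2:**
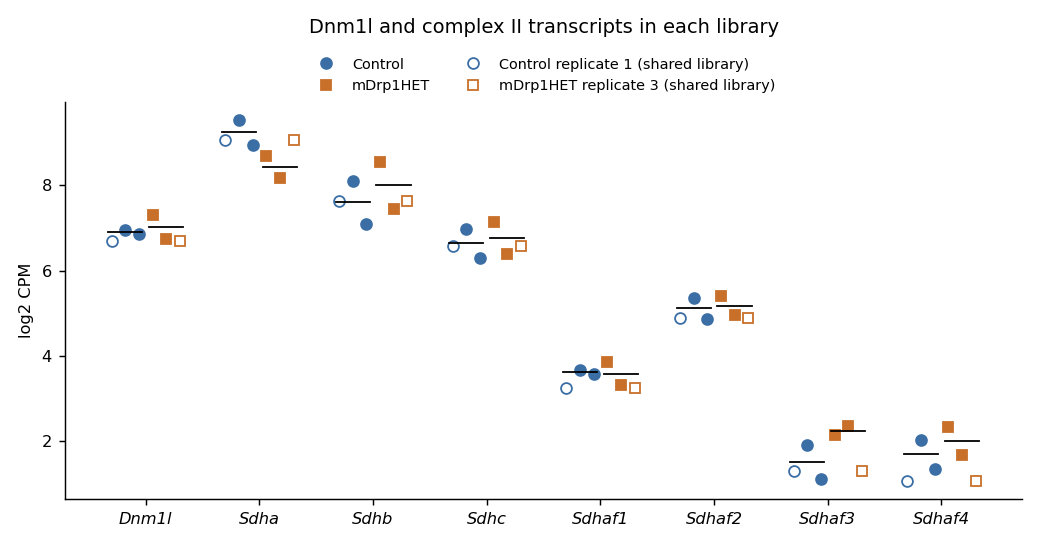
Deposited log2 CPM of Dnm1l and 7 complex II genes in each library. Circles are Control and squares mDrp1HET libraries, open symbols mark the shared library, and lines give the mean of the 2 filled symbols of a group. The Dnm1l values of both groups overlap.

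In the labelled comparison of mDrp1HET with Control, 0 genes passed the threshold with limma (lowest adjusted p = 0.753), and voom on recovered reads also called 0. With limma 459 genes had an unadjusted p under 0.05, fewer than the 588 that evenly spread p-values would give. The authors' deposited table had 10 genes with a p under 0.05 and a lowest p of 0.0476. With 1 value in both groups the statistic behind that column cannot give a p under 0.0474, so these values lie near its floor. The smallest unadjusted p values among genes with higher means in mDrp1HET belonged to Rpph1, the RNA of ribonuclease P, Cep85l, Noct, a circadian phosphatase, Lrrc30 and Nid1, a basement membrane protein. Their labelled log2 fold changes were 1.40, 1.17, 1.16, 1.06 and 0.82. Among genes with lower means they belonged to Igfn1 (-2.00), Flnc, the muscle filamin (-0.74), Hspb6, a small heat shock protein (-0.77), Smox (-0.74) and Ppip5k1 (-0.75). None of these 10 passed. In simulated data with 1 library in both groups, 0 of the changed genes were called, even at a change of 3 on the log2 scale.

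Without the shared library, 22 genes passed the threshold between the 2 Control and 2 mDrp1HET libraries, 17 higher and 5 lower in mDrp1HET. With limma 1949 genes had an unadjusted p under 0.05, where evenly spread p-values would give 588. Of the 1949, 1565 were higher and 384 lower, and with median centring, which moved the median of all genes from 0.20 to 0.04, 1083 were higher and 893 lower. Among the lower genes, Igfn1 was lower by a log2 fold change of -3.00 (SE 0.36, adjusted p = 0.0101) and Ankrd1, a stretch-responsive ankyrin protein, by -1.77 (SE 0.28). Myh14, a nonmuscle myosin heavy chain, and Naca, whose long form is a muscle transcription cofactor, had log2 fold changes of -1.70 and -1.64.

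Among the genes taken by the naming rule, the largest rises in the 4-library comparison were in Odf3l2 (log2 fold change 2.72, SE 0.31, adjusted p = 0.00694), Cebpd, a stress-responsive transcription factor (2.16, SE 0.34), and Rpph1 (2.10, SE 0.20, adjusted p = 0.00496). Cep85l (1.76), Noct (1.74), the small nuclear RNA Rn7sk (1.72), Ppp1r3c, a glycogen-targeting phosphatase subunit (1.63), Nova1 (1.60), Lrrc30 (1.58) and the ribosomal protein gene Rps14 (1.48) followed. Outside the rule, the other genes called were Ifi205 (1.46), Ces1d (1.38), the pyruvate carrier subunit Mpc1 (1.33), Asb5 (1.27), Nid1 (1.23), B230312C02Rik (2.59) and Gm4342 (1.42). Genes in several near-identical copies, such as Rps14, Gm4342, Naca and Ces1d, are uncertain, because it is not given how shared reads were counted. Median centring of the 4 libraries and a fit without the intensity trend each called 0 genes, and quantile normalization 1, Rpph1. The other ways of splitting these 4 libraries into pairs, which mix the groups, called 5 and 19 genes past the threshold. At an unadjusted p under 0.05 they had 568 and 135 genes, against 1949 in the real split. Log2 fold changes across genes also fell with transcript GC content (Spearman -0.39, across genes, which are not independent replicates), and removal of that trend left 17 calls, 14 of them among the 22.

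**Figure D3:**
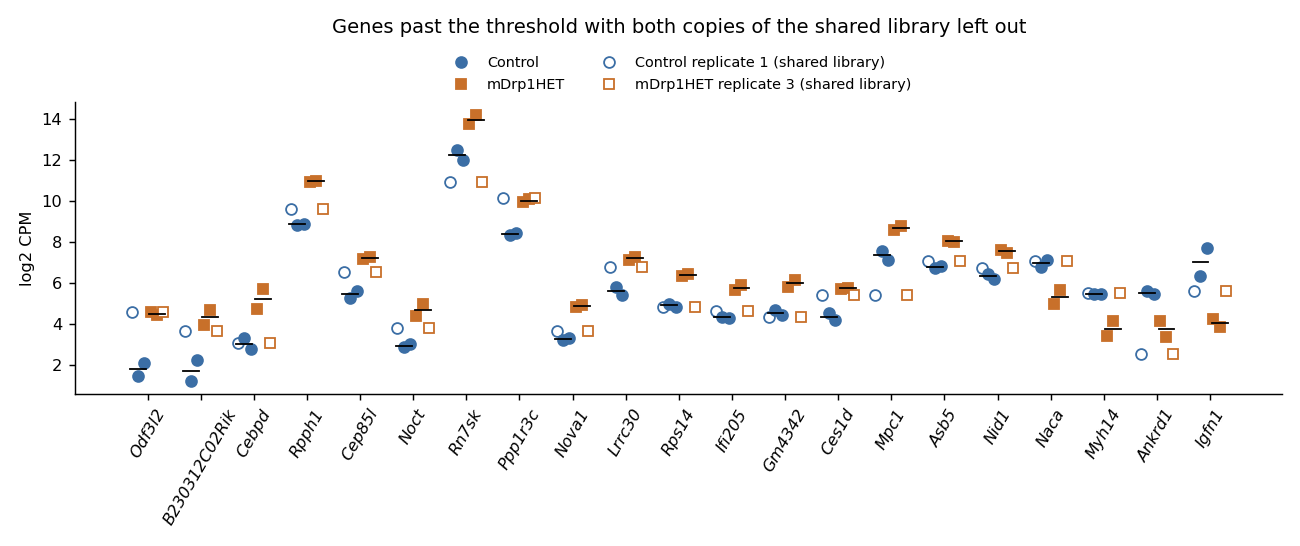
Deposited log2 CPM of the genes past the threshold in the 4-library comparison, apart from 1 that is not reported, ordered by log2 fold change from 2.72 to -3.00. Circles are Control and squares mDrp1HET libraries, open symbols mark the shared library, which entered neither group, and lines give the mean of 2 libraries. The filled symbols of each gene do not overlap between groups.

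The 4 libraries also differed in depth and in abundant noncoding RNA. The Control libraries had 28664508 and 25019293 reads and the mDrp1HET libraries 15782298 and 10394761. Rn7sk took 0.584% and 0.419% of the reads in Control and 1.39% and 1.90% in mDrp1HET libraries. The ribosomal RNA precursor Rn45s took 1.59% in mDrp1HET replicate 1 and between 5.18% and 8.30% in the other columns.

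The values of the shared library lay near the 2 mDrp1HET libraries for some of these genes and near the 2 Control libraries for others. Odf3l2 stood at 4.59 in the shared library, against 1.80 ± 0.42 in Control and 4.52 ± 0.12 in mDrp1HET libraries (SD, n = 2 each). Rps14 stood at 4.86, against 4.92 ± 0.10 and 6.40 ± 0.07 (SD, n = 2 each). With the library counted in mDrp1HET alone, 2 genes passed, Odf3l2 and Ppp1r3c, and counted in Control alone, 2 genes passed, Rps14 among them. With limma 449 and 2841 genes, in that order, had an unadjusted p under 0.05. Over all 11768 genes the shared library lay nearer the Control libraries. Its median absolute log2 difference was 0.222 and 0.194 from Control replicates 2 and 3. From mDrp1HET replicates 1 and 2 it was 0.457 and 0.310, and these 2 differed from each other by 0.320.

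Of 46 gene lists, 16 passed the threshold in the labelled comparison, 5 higher and 11 lower in the libraries labelled mDrp1HET, and with quantile normalization 10 passed, 6 higher and 4 lower. Heat shock protein genes were the list with the lowest p, and they lay lower. All genes together had a median log2 fold change of 0.13 in the labelled comparison, which fell to 0.02 with median centring, so list medians are given relative to all genes. Heat shock genes had a median 0.51 below that of all genes in the labelled comparison (camera adjusted p = 4.78e-07) and 0.76 below it in the 4-library comparison, where 17 of 21 members lay below the median of all genes. With an estimated correlation between genes, adjusted p = 0.913 for this list and for each of the other 15 lists that passed. In that test 0 of the 16 lists passed. The correlation was estimated from the labelled columns, whose spread within groups includes the distance between the groups. In the 4-library comparison, with 2 libraries per group, the lowest adjusted p with an estimated correlation was 0.933. These values therefore neither uphold the calls nor show that they fail. Fry asks whether the genes of a list move one way and does not compare them with other genes. It gave 0.967 for each of the 16 lists. It was run only on the labelled columns, where 1 library stands in both groups, so a low p was hardly possible. The fry result therefore does not decide whether the calls hold. Adjusted over the list alone, 5 of 21 members passed in the 4-library comparison, all lower, and 0 in the labelled one. They included the lens and muscle chaperone Cryab (-1.38, SE 0.27), Hspb6 (-1.15, SE 0.22), the co-chaperone Hsph1 (-1.06, SE 0.23) and the transcription factor Hsf1 (-0.72, SE 0.24), and adjusted over all genes 0 of 21 passed. Leaving out any 1 column kept the list past the threshold (highest adjusted p = 0.000718, without mDrp1HET replicate 3). In 4 of the 6 leave-outs the shared library still stood in both groups, so that without mDrp1HET replicate 1 or 2, or Control replicate 2 or 3, 1 group had only 1 library of its own. In the 4-library comparison 17 lists passed, and in the other splits of these libraries 26 and 8.

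Genes of the citric acid cycle, of mitochondrial chaperones and proteases and of glycolysis and glycogen also lay lower relative to all genes. The lists of respiratory chain subunits did not pass in the main test of the labelled comparison, although array weights called that of complex V. Citric acid cycle genes had a median 0.22 below that of all genes (camera adjusted p = 0.00014, and adjusted p = 0.913 with an estimated correlation), with 21 of 23 members below the median of all genes in the 4-library comparison. The 4-library values of Ogdh, a subunit of the 2-oxoglutarate dehydrogenase complex, Pcx, pyruvate carboxylase, and Mdh2, malate dehydrogenase, were -0.71 (SE 0.22), -0.62 (SE 0.22) and -0.52 (SE 0.25), and 0 of 23 passed over the list alone. Mitochondrial chaperones and proteases were 0.28 below all genes (adjusted p = 0.00823), and 1 of 14 passed over the list alone, the protease Spg7 (-0.91, SE 0.23). Glycolysis and glycogen genes were 0.24 below (adjusted p = 0.00171), and 4 of 24 passed over the list alone. Of these the hexokinase Hk2 (-0.88, SE 0.20), glycogen synthase Gys1 (-0.77, SE 0.22) and phosphofructokinase Pfkm (-0.72, SE 0.22) fell, and Mpc1 rose. Only Mpc1 passed over all genes among the members of these lists, and its value in the shared library lay below those of both groups. Leaving out mDrp1HET replicate 2 ended the calls of these 3 lists (adjusted p = 0.212, 0.316 and 0.0666), leaving out Control replicate 2 that of chaperones and proteases (0.0505), and quantile normalization that of glycolysis (0.347).

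Fatty acid oxidation genes had a median 0.15 below that of all genes (camera adjusted p = 0.0159, and adjusted p = 0.913 with an estimated correlation), and 0 of 30 members passed over the list alone. The acetyltransferase Crat and Cpt1b, which admits long-chain fatty acids to mitochondria, had 4-library log2 fold changes of -0.71 (SE 0.22) and -0.71 (SE 0.42), and Cpt2 one of -0.36 (SE 0.27). The hydratase Echs1 went the other way (0.48, SE 0.29), and 13 of the 30 labelled fold changes lay above 0. Relative to all genes, 22 of the 30 members lay below the median in the 4-library comparison. Regulators of mitochondrial biogenesis passed in the lower direction (adjusted p = 0.0183) although their own median fold change was 0.05 and their mean was -0.06, with the coactivator Ppargc1b at -0.90 (SE 0.34) and the protease Lonp1 at -0.54 (SE 0.22) in the 4-library comparison. Fusion and inner membrane genes passed at an adjusted p of 0.0491, and 3 of 17 passed over the list alone, of which the fusion protein Mfn2 (-1.03, SE 0.21) and Spg7 fell and the protease Yme1l1 (0.64, SE 0.20) rose. Spg7, Yme1l1 and Afg3l2 are also members of the chaperone and protease list, which shares Lonp1 with the biogenesis list. The calls of these lists are therefore not independent. Calcium handling genes were 0.15 below all genes (adjusted p = 0.024), and of 27 members the calcium release channel Ryr1 (-1.56, SE 0.38) and the junction protein Jph2 (-0.90, SE 0.25) fell and Asph (0.71, SE 0.20) rose over the list alone. No member of these 4 lists passed over all genes. Leaving out single columns ended the calls of these 4 lists. Without Control replicate 2 the adjusted p was 0.913 for fatty acid oxidation, whose direction turned, 0.105 for biogenesis and 0.351 for fusion. Without mDrp1HET replicate 2 these lists had 0.774, 0.0505 and 0.403, and fusion had 0.0859 without mDrp1HET replicate 3. Calcium handling had 0.163 without Control replicate 1, 0.108 without Control replicate 3 and 0.366 without mDrp1HET replicate 1. Quantile normalization ended them too (0.0568, 0.0506, 0.138 and 0.399), removal of the GC trend ended that of calcium handling (0.101), and fusion did not pass in the 4-library comparison (0.0614) or without the intensity trend (0.0544).

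Markers of several other cell types of a muscle piece lay higher in the libraries labelled mDrp1HET, and those of vessels and tendon lay lower. Fibro-adipogenic progenitor markers had a median 0.32 above that of all genes (camera adjusted p = 0.000218, and adjusted p = 0.913 with an estimated correlation), and macrophage markers 0.35 above (adjusted p = 0.00137, likewise 0.913). Without any 1 column both had adjusted p values under the threshold, the highest being 0.04996 without mDrp1HET replicate 2 and 0.0406 without Control replicate 3, where the shared library stood in both groups and 1 group had only 1 library of its own. Over the list alone 7 of 15 fibro-adipogenic markers rose in the 4-library comparison, among them Smoc2 (1.05, SE 0.23), Clec3b (1.04, SE 0.27), the progenitor receptor Pdgfra (0.90, SE 0.22) and the collagen Col3a1 (0.85, SE 0.22). Of 16 macrophage markers 6 rose, among them the complement gene C1qa (0.99, SE 0.28), the leukocyte antigen gene Ptprc (1.06, SE 0.36), H2-Aa (0.97, SE 0.33) and the scavenger receptor gene Cd163 (0.74, SE 0.21). Adjusted over all genes, 0 of the 15 and 0 of the 16 markers passed. Values of single genes are not taken relative to all genes, whose median was 0.20 in the 4-library comparison. Extracellular matrix genes were 0.14 above all genes (adjusted p = 0.00711), and 5 of 28 rose over the list alone. These included Nid1, Lox (0.73, SE 0.22) and Col3a1, which stands in the fibro-adipogenic list too. Without mDrp1HET replicate 2 this call was lost (adjusted p = 0.316).

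Interferon-stimulated genes were 0.21 above all genes (camera adjusted p = 0.024, and adjusted p = 0.913 with an estimated correlation), with Ifit1 at 1.02 (SE 0.37), Ifi27l2a at 0.81 (SE 0.31) and 0 of 22 past the threshold over the list alone. Adipocyte markers were 0.34 above (adjusted p = 0.0389), and Nnat (2.07, SE 0.40), the hormone gene Lep (1.92, SE 0.41) and Acvr1c (1.11, SE 0.32) rose over the list alone, 3 of 12. Endothelial markers were 0.22 below all genes (adjusted p = 0.0183) and smooth muscle and pericyte markers 0.31 below (adjusted p = 0.0235), and 0 members passed over either list. Members went both ways, with the endothelial receptor Kdr at -0.95 (SE 0.31) and the junction protein Cldn5 at 0.80 (SE 0.44), and the smooth muscle myosin Myh11 at -1.17 (SE 0.40) and the pericyte gene Rgs5 at 0.57 (SE 0.29). Tendon markers were 0.25 below (adjusted p = 0.0323), and 1 of 10, the matrix protein Comp, fell over the list alone (-1.54, SE 0.40), with Tnmd at 0.49 (SE 0.36). In these 5 lists 0 members passed when adjusted over all genes. All 5 calls depended on single columns. Without Control replicate 1 interferon genes had an adjusted p of 0.0545. Without Control replicate 2 adipocyte, endothelial, smooth muscle and tendon markers had 0.173, 0.234, 0.536 and 0.377, and without Control replicate 3 interferon genes, adipocyte and tendon markers had 0.117, 0.663 and 0.271. Tendon markers had 0.38 without mDrp1HET replicate 1. Without mDrp1HET replicate 2 interferon genes, endothelial and smooth muscle markers had 0.188, 0.316 and 0.188, and without mDrp1HET replicate 3 adipocyte, smooth muscle and tendon markers had 0.948, 0.0641 and 0.526. Removal of the GC trend ended the endothelial (0.0874) and smooth muscle (0.0903) calls, camera without the intensity trend the adipocyte call (0.0583), median centring the tendon call (0.145) and quantile normalization the smooth muscle (0.108) and tendon (0.147) calls.

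**Figure D4:**
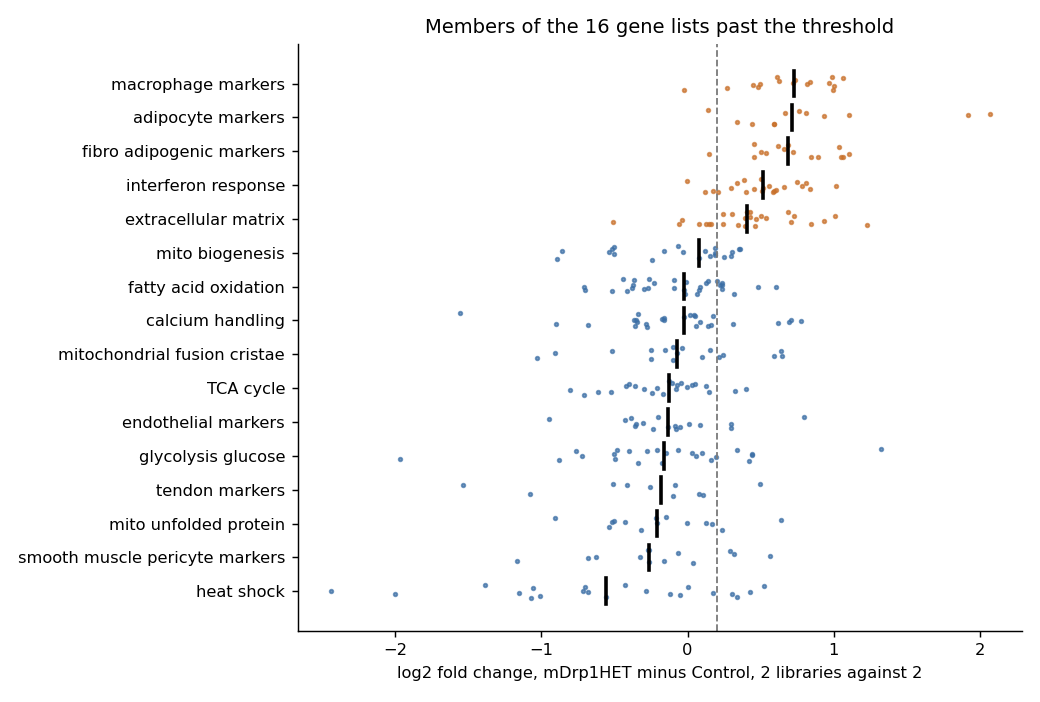
Log2 fold change, mDrp1HET minus Control, of each measured member of the 16 gene lists past the threshold in the labelled comparison, as measured in the 4 libraries left without the shared library (2 against 2). Black bars are list medians and the dashed line is the median of all genes, 0.20. Orange lists were called higher and blue lists lower, and the median of heat shock genes is -0.56.

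The lists that did not pass in the labelled comparison included the nuclear-encoded subunits of complexes I, III, IV and V (camera adjusted p = 0.921, 0.815, 0.754 and 0.449), mitochondrial fission genes (0.83) and mitochondrial ribosomal proteins (0.921). Fis1 and Mff, receptors of Drp1 on the outer mitochondrial membrane, had 4-library log2 fold changes of 0.56 (SE 0.25) and 0.46 (SE 0.22). Mitophagy and autophagy genes (0.754), the integrated stress response (0.376), endoplasmic reticulum stress (0.352), oxidative stress (0.754), atrophy (0.32), slow fibre (0.392), fast fibre (0.191) and proteasome genes (0.449) did not pass either. The same held for denervation (0.132), PPAR target (0.187), regeneration (0.225), immediate early (0.253), lipid storage (0.342), lipid and cholesterol synthesis (0.342), insulin signalling (0.546), inflammation (0.578), circadian clock (0.578), proliferation (0.638) and muscle growth genes (0.754). It also held for nerve (0.546), heart (0.638) and erythroid markers (0.736). Leaving out single columns brought some of these lists past the threshold. Higher were complex IV (0.0468) and slow fibre genes (0.038) without Control replicate 2, slow fibre genes without mDrp1HET replicate 2 (0.0471), and atrophy genes without Control replicate 1 (0.00753) or mDrp1HET replicate 1 (0.0103). Lower were immediate early genes without Control replicate 1 (0.0318) or mDrp1HET replicate 2 (0.0152), and fast fibre (0.0118) and circadian genes (0.046) without Control replicate 2. Complex V (0.0131), PPAR target (0.000648) and lipid storage genes (0.0131) were lower without Control replicate 3, and PPAR target (0.0231) and mitochondrial ribosomal protein genes (0.0366) without mDrp1HET replicate 1. Denervation genes were lower without mDrp1HET replicate 2 (0.00936) or 3 (0.027), and fast fibre genes without mDrp1HET replicate 3 (0.027). Cytosolic ribosomal proteins had an adjusted p of 0.0532 in the labelled comparison, and passed there in the higher direction with median centring (0.00723), quantile normalization (0.00297) and removal of the GC trend (0.0216). Without Control replicate 2, mDrp1HET replicate 2 or mDrp1HET replicate 3 they passed as well (0.0289, 0.000664 and 0.0163). Their adjusted p was 6.99e-05 in the 4-library comparison (adjusted p = 0.933 with an estimated correlation), where 21 of 69 members rose over the list alone, among them Rps14 and Rpl41 (1.12, SE 0.25).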

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

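The 8 settings that leave out both copies of the shared library, remove the GC trend or use voom, and the estimated correlation without both copies, were chosen after the data were seen. The labelled count of 0 genes past the threshold did not change under any planned normalization, offset, filter or variance model, and ranged from 0 to 2 when single columns were left out, with 2 without Control replicate 1 or without mDrp1HET replicate 3. Both of these remove the shared library from 1 side. In simulated data with 1 library in both groups, 0 of the changed genes were called. That the labelled count stayed at 0 therefore does not show that it is robust. Array weights called 0 genes with a lowest adjusted p of 0.0591. With them 3935 genes had an unadjusted p under 0.05, against 459 in the main fit. Leaving out both copies gave 22 genes, and from there median centring gave 0, no intensity trend 0, quantile normalization 1, removal of the GC trend 17 and voom 51, which held all 22. The cause of these differences was not tested. The log2 fold change of Dnm1l passed no threshold and ranged from -0.13 to 0.18 when single columns were left out.

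Of 46 lists, 16 passed, and 10 with quantile normalization and 10 with a minimum mean log2 CPM of 3, which tests 43 lists. An estimated correlation, drawn from columns whose spread includes the distance between the groups, gave 0, and leaving out single columns between 10 and 17. Fry gave 0 as well, but was run only with 1 library in both groups, where a low p was hardly possible. Camera without the intensity trend gave 14, without the fusion and adipocyte lists, and on ranks 15. The filter at 3 ended the calls of fusion, biogenesis, calcium handling, interferon, adipocyte, endothelial, tendon and smooth muscle lists, array weights that of biogenesis (and called complex V, PPAR target and fast fibre lists), and the filter at 1 and ranks that of fusion. Without both copies 17 passed, 9 with quantile normalization and 0 with an estimated correlation. Array weights turned the direction of adipocyte markers (adjusted p = 0.49) and tendon markers (0.25), and fatty acid oxidation ranged from 1.41e-07 to 0.913 when single columns were left out. The cause was not tested. Of 778 list values under planned settings 82 lost the call, 28 gained one and 3 turned direction. Of 3242 gene values 4 gained a call and 0 lost one, and 45 uncalled values changed sign. No gene was called in the labelled comparison, so no call could be lost. The robust prior and the Student statistic were not run for lists, since camera has no such setting. The depth of mDrp1HET replicate 2, 10394761 reads, limits genes near 1 CPM most.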

Other observations

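The 4-library comparison, the removal of trends on it and the tests of the shared library, Dnm1l, GC content, length and the region around Dnm1l were chosen after the data were seen. For GC content, length and the region, the outcome that would decide was written before its result was seen, and the splits were planned.

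In the 4-library comparison, of 2 Control and 2 mDrp1HET libraries, 5 of 23 atrophy-linked genes rose over the list alone, among them the transcription factors Foxo1 (log2 fold change 1.32, SE 0.25) and Klf15 (1.08, SE 0.24), Klhl38 (0.92, SE 0.23) and the stress gene Ddit4 (1.86, SE 0.32), while the list as a whole did not pass (camera adjusted p = 0.191). The developmental myosins Myh3 and Myh8 fell over the lists of denervation and regeneration genes alone, at -1.36 (SE 0.28) and -1.15 (SE 0.22), and the muscle transcription factor gene Myog rose (1.38, SE 0.39). The denervation list passed in the lower direction (adjusted p = 0.0426, and adjusted p = 0.933 with an estimated correlation), and not with median centring, quantile normalization, removal of the GC trend or no intensity trend. None of these genes passed over all genes. Their fold changes are not taken relative to all genes, whose median was 0.20. Of 1949 genes with an unadjusted limma p under 0.05, 1565 were higher. The atrophy list had a median 0.09 above that of all genes, and stood at -0.08 relative to them after removal of the GC trend. Slow fibre genes had a median log2 fold change of 1.02 and did not pass (adjusted p = 0.194), and over the list alone 1 of 10 rose, Pln (1.52, SE 0.33). Myh7, the slow myosin, stood at 7.34 log2 CPM in mDrp1HET replicate 1 and between 1.31 and 3.56 in the other columns, and the slow troponin Tnnt1 at 6.81 and between 0.20 and 3.19.

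A few genes on chromosome 17 differed widely between libraries of the same group. They were singled out after their values were seen. Rnaset2b stood at 2.35 log2 CPM in Control replicate 1, its copy in mDrp1HET replicate 3 at 2.37, and the other columns between 5.76 and 6.90. Rnaset2a, its near-identical copy, stood at 2.08 in mDrp1HET replicate 2 and between 5.61 and 6.56 in the other columns. Mpc1 stood at 5.45 in the shared library and between 7.13 and 8.80 elsewhere. Rnaset2b lies at 6978860 to 6998193, Rnaset2a at 8128580 to 8148246 and Mpc1 at 8283787 to 8297667 (RefSeq GRCm38.p6). How reads shared by the Rnaset2 copies were counted is not given in the sources used here, so their separate values are uncertain.

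Control replicate 1 and mDrp1HET replicate 3 are consistent with the same reads entered under both labels, since 96.3% of genes had exactly 2 times the reads. Sequencing 1 RNA on separate occasions would leave about as many even as odd read numbers, and 97.4% of genes in Control replicate 1 had an even number, against 49.4% to 50.8% in the other columns. Separate animals with similar muscle are argued against by the chi-square per gene of 0.00367, against a lowest value of 52.8 in the other pairs. Over all genes the shared library lay nearer the Control libraries, with median absolute log2 differences of 0.222 and 0.194 from Control replicates 2 and 3. From mDrp1HET replicates 1 and 2 they were 0.457 and 0.310. The 2 mDrp1HET libraries lay 0.320 apart, so these distances do not settle the group. Which group the library belongs to stays open, and no biological explanation of the matching columns was tested.

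Dnm1l transcripts in the libraries labelled mDrp1HET were not detectably lower. A fall to 0.5 of Control hidden by the shared library lies outside the 4-library interval, whose lower bound was -0.40 on the log2 scale. That interval rests on limma's variance, which draws on all genes, and the 2 mDrp1HET libraries had an SD of 0.41. It therefore argues against such a fall only as far as that variance holds for Dnm1l. Dnm1l has a low GC content (40.9%), and relative to all genes after removal of the GC trend it was at -0.33 (95% interval -0.82 to 0.17), so a smaller fall stays open. Continued transcription of the recombined allele, wrong labels and Dnm1l transcripts of other cells in the muscle piece stay open and were not tested. A hypothesis that genes within 10 Mb of Dnm1l differ more often, through a chromosome segment carried with the allele, was not borne out. There 15 of 123 genes (12.2%) had an unadjusted p under 0.05, against 16.4% of the other genes, a ratio of 0.742 (Fisher's exact p = 0.269). That test runs across genes, which are not independent replicates.

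The smooth GC trend was too small to make up the folds of the 22 genes called in the 4-library comparison. The median log2 fold change was 0.49 in genes of the lowest GC content (31.0% to 41.6%) and -0.03 in those of the highest (57.8% to 70.7%). The 22 genes were picked for large folds in these same data, so removing the trend could hardly have taken most of their folds away. Whether GC content helped single genes past the threshold is not decided by the test on these 22 genes. After removal of the GC trend the median absolute log2 fold change of these genes, relative to all genes, went from 1.53 to 1.47, 0.965 times its earlier value (95% bootstrap interval 0.878 to 1.11), where all 22 kept their sign and 14 their call, and why the others lost theirs was not tested. All 22 genes share the same 4 libraries, so the interval does not measure the spread between libraries. Fold changes across genes were hardly related to transcript length (Spearman 0.0039), and removal of what length trend there was left 0.951 times the earlier value (0.859 to 1.02) and called 30 genes. Differences between single libraries, library depth, which was lower in both mDrp1HET libraries, and genotype stay open. The other splits of the 4 libraries called 5 and 19 genes against 22, and had 568 and 135 genes with an unadjusted p under 0.05 against 1949.

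Of the 10 splits of the 6 columns into groups of 3, 10 gave at least the 0 genes of the real split (highest other 0), and 5 gave at least its 16 lists (highest other 24). These splits are too few for a share under 0.05. Because 1 library stands in both groups, the split that exchanges its copies repeats the real one (461 and 459 genes with an unadjusted p under 0.05, 16 lists each), the splits with 24 lists repeat each other, and 4 of the 10 put both copies in 1 group. A count set against 0 genes is met by any split.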
